A study of Homo sapiens with 2 samples.

How the data were processed

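IRF1, a transcription factor of the interferon response, was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in NB4 cells. NB4 is an established human acute promyelocytic leukemia line that carries the PML-RARA fusion. Per the labels' protocols, cells received the solvent DMSO or all-trans retinoic acid (ATRA), the differentiating drug used in this leukemia, for 4 hours. There were 2 libraries, 1 per group, so no spread between replicates can be given. Per the labels' protocols, chromatin was fixed with formaldehyde and sonicated, and libraries were amplified by PCR from input and immunoprecipitated DNA.

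The analysis used 1 deposited list of binding summits, which per the file headers carries the name of the 4 hour retinoic acid library. Values of the control library, signal tracks and reads were not analysed here, so no comparison of treated with control cells was made. Bowtie2 2.2.9, MACS 1.4.2 and the build hg38 are named in the submitters' processing notes. Per the file headers, a file of summits was annotated with HOMER's annotatePeaks.pl against hg38. The background of the calling, its threshold and the handling of duplicate and multiply mapped reads are not given in the sources used here. If the control library was the background, the list holds sites enriched over control cells, and a gene without a summit could be bound to the same extent in both. Each row is a position of 1 base with a peak score, a signed distance to the nearest transcription start site (TSS), a genomic class and the nearest gene. The deposited peak score is the authors' own value, its scale is not stated in the file headers, and it was used only to describe, rank and compare summits within this list, so a difference in score has no physical unit. The read depth behind a summit is unknown. The peak numbers ran from 1 to 1986 with none missing. Positions are 1-based on hg38.

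Genes were matched by Entrez identifier to a RefSeq gene table of GRCh38.p14, in which the nearest gene of 1977 of 1986 summits was found, and current symbols are used. The gene-level tests ran on 19974 protein-coding genes of the autosomes and chromosome X. A gene counted as having a summit when it was the authors' nearest gene of at least 1 summit within 10 kb of its TSS. A gene that shares a promoter with its neighbour can be missed in this way. For each of 19 gene lists the share of such genes was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 19 lists and a threshold of 0.05. No gene belonged to more than 1 list. Each list was also placed among 10000 random lists of its size, matched on gene neighbourhood length in 20 classes. Odds ratios are conditional estimates with exact 95% intervals, and shares have 95% Wilson intervals. Median scores were compared by two-sided permutation tests with 100000 resamples. All these tests run across the summits or genes of 1 library. They describe this list, not the effect of the treatment, and intervals cover counting error only. A share of 0 was given the upper limit of 3 counts.

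The lists, their test and the rule for named genes were fixed before the data were examined. The pooling of the 4 lists that had no gene with a summit was chosen afterwards. The chromosome 21 block (summits at most 100 kb apart, a distance raised after a shorter one had split the block), the comparisons of promoter with other scores and of the 100 highest summits with the rest, and the tests of gene families, repeats and exons were chosen after seeing the data. The rule names the genes of the 10 highest-scoring summits within 10 kb of a TSS, up to 4 members of each list with the highest-scoring summits, IRF1, RARA and PML in any case, and the 3 summits farthest from a TSS among the 100 highest scores. Some genes that the rule takes are not reported here. Planned tests of sequence motifs, including the interferon-stimulated response element, and the genomic expectation of the annotation classes were not run, because no genome sequence was used here. Matching on promoter CpG content was not run for the same reason, and distances to all RefSeq TSSs were not run because strand was not used here. The alternatives tried were the 993 summits with the highest score, TSS distances of 1 kb and 5 kb, the nearest gene at any distance, gene spans extended by 10 kb, summits under 200 bp apart merged, and omission of a dense block on chromosome 21. The list test was tested on simulated data for the same 19974 genes and 19 lists. With 4 lists per simulation raised 10-fold it recovered 99.2% of the raised lists of at least 20 genes, with 5-fold raises 54.3%, and with no raise it called 0% of lists. Unraised lists were called at 0.333% beside 10-fold raises and at 0.533% beside 5-fold raises. Genes were simulated independently, whereas some listed genes are neighbours. These rates and the p-values of the lists leave out such clustering. Computations used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.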

Results

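The deposited list held 1986 IRF1 summits from NB4 cells treated with all-trans retinoic acid for 4 hours. There was 1 library in the treated group and 1 in the control group, and the values of the control library were not analysed here. The data therefore list sites called in the treated cells, with no measured gain or loss under treatment. The background of the calling is not known, and if it was the control library, the sites are those enriched over control cells and a missing summit does not mean missing binding. Summits lay on 23 chromosomes. The authors' peak score ranged from 8.28 to 321, with a median of 25.2 and quartiles of 17.7 and 44.0. Chromosome 21 held 170 summits, of which 133 lay between positions 8153380 and 8471377 on its short arm, all with a non-coding RNA as the nearest gene. This block made up 6.70% of the list, and counts include it unless stated otherwise. Without it 1853 summits remained, of which 358 were promoter summits (19.3%).

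To describe where IRF1 was located, the summits were sorted by genomic class. Intergenic sequence held 731 summits (36.8%, 95% Wilson interval 34.7 to 39.0), introns 698 (35.1%, 33.1 to 37.3) and promoters 384 (19.3%, 17.7 to 21.1). A further 39 summits lay in 5′ UTRs, 55 at transcription termination sites, 37 in non-coding transcripts, 30 in other exons and 12 in 3′ UTRs. The 539 summits within 1 kb of a TSS were centred on it, with a median signed distance of 9 bp, and 217 of them lay within 100 bp. At the other end, 231 summits (11.6%) were more than 100 kb from any TSS.

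**Figure D1:**
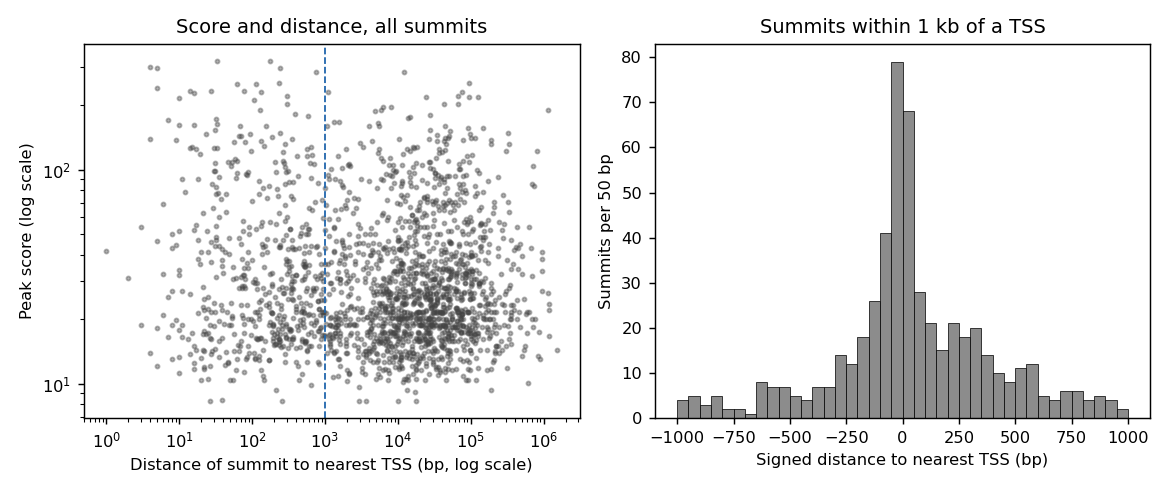
Left, peak score (log scale) of each of the 1986 summits against its distance to the nearest TSS in bp (log scale), with a dashed line at 1 kb; right, number of summits per 50 bp bin of signed distance for the 539 summits within 1 kb. High scores occur both at TSSs and far from them, and the summits near a TSS pile up around it, 217 of them within 100 bp.

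The strongest summits were at TSSs more often than the rest. Among the 100 highest scores, 49 lay within 1 kb of a TSS, against 490 of the other 1886 (odds ratio 2.74, 95% interval 1.78 to 4.19, two-sided Fisher's exact p = 2.39e-06). The median score of promoter summits was 27.6, against 24.8 for all others, a difference of 2.86 (two-sided permutation test over 384 and 1602 summits, p = 0.0234). Without the chromosome 21 block this difference was 2.17 and did not pass the threshold (permutation p = 0.113), whereas the odds ratio of the top 100 was 2.64 (Fisher's exact p = 4.5e-06).

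Among the 10 highest summits within 10 kb of a TSS were those of PSME1, TAP2 and ERAP1, from the MHC class I list, and of ISG15 and PARP9, from the interferon-stimulated list. The top summit, with a score of 321, was at chromosome 14 position 24136191, 33 bp downstream of the TSS of PSME1, a subunit of the interferon-inducible proteasome activator. SHFL, an interferon-induced inhibitor of ribosomal frameshifting, followed with 320.5 at chromosome 19 position 10086294, in its 5′ UTR. TAP2, a subunit of the peptide transporter of the endoplasmic reticulum, had a score of 301 at chromosome 6 position 32838774. The proteasome assembly chaperone PSMG4 had 299, and the peptide-trimming aminopeptidase ERAP1 had 297. PARP12, an antiviral ADP-ribosyltransferase, had 287, RBCK1, a component of the linear ubiquitin ligase, had 253, and the ubiquitin-like modifier ISG15 had 251. The non-coding RNA gene CARINH, listed under its earlier symbol C5orf56, had 250.0 at chromosome 5 position 132410885, and PARP9 had 240.0. Of the 100 highest summits, 54 lay within 10 kb of the TSS of a protein-coding gene, and for 19 of these the gene belonged to the interferon-stimulated or MHC class I list.

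Interferon-stimulated genes were the list most often next to a summit. Of 60 listed genes, 40 were the nearest gene of a summit within 10 kb (66.7%, Wilson interval 54.1 to 77.3), against 3.17% of the other protein-coding genes. The odds ratio was 61.1 (34.6 to 111), with an adjusted p of 1.52e-43 by Fisher's exact test. In 38 of the 40 the best summit lay within 1 kb of the TSS, and in 29 within 100 bp. The highest scores were those of ISG15, PARP9 (240.0), APOL2, an apolipoprotein L gene (233), and USP18, the protease that removes ISG15 from its targets (212). The 20 members that were not the nearest gene of a summit within 10 kb included IFI27, IFI44, IFI44L, IFITM1, IFITM2, IFITM3, MX2, OAS2 and BST2. DTX3L, RSAD2, TRIM5 and TRIM69 were also among these, although a summit lay within 10 kb of their spans.

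The MHC class I presentation list held 13 of 22 genes with a summit (59.1%, 38.7 to 76.7; odds ratio 42.3, 16.7 to 113; adjusted Fisher's exact p = 2.21e-13). PSME1, TAP2, ERAP1, TAP1 (231), PSMB8 (229), TAPBP (221), PSMB10, TAPBPL, PSME2, PSMB9 and B2M all had a summit with a score above 100. Of the heavy chain genes, HLA-C had a summit with a score of 27.4, and HLA-B, HLA-E, HLA-F and HLA-G had none within 10 kb as nearest gene. HLA genes are related in sequence, and how the authors placed reads that match more than 1 gene is not known. The chaperones CALR, CANX and PDIA3 and the transactivator NLRC5 had none within 10 kb either, although a summit farther from its TSS had NLRC5 as the nearest gene. The TAP and immunoproteasome genes lie side by side on chromosome 6, and the TAP1 summit at position 32853840 lies between the spans of TAP1 and PSMB9.

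**Figure D2:**
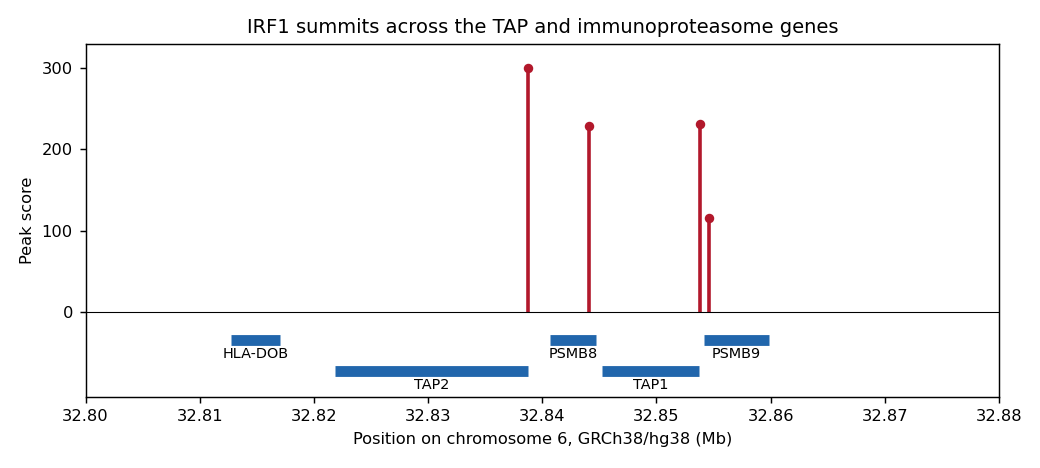
Positions on chromosome 6 (hg38, Mb) and peak scores of the 4 summits across the TAP and immunoproteasome genes, as stems from 0; blue bars are the RefSeq gene spans. The TAP2, PSMB8 and TAP1 summits, with scores of 301, 229 and 231, lie at -4, -16 and 131 bp from the TSS. A lower PSMB9 summit has a score of 115.

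Of 17 listed MHC class II genes 1 had a summit, HLA-DOA, at -9500 bp from its TSS with a score of 98.0 (5.88%, Wilson interval 1.05 to 27.0; adjusted Fisher's exact p = 0.698). CIITA, the master regulator of this group, CD74 and the listed DR, DP, DQ and DM genes had none. The list of guanylate binding proteins, interferon-induced GTPases, also held IRGM, which is not one of them. This list had 2 of 8 genes with a summit, GBP2 (49.0) and GBP1 (30.7). It did not pass the threshold (odds ratio 9.61, 0.947 to 53.9, adjusted Fisher's exact p = 0.0593).

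**Figure D3:**
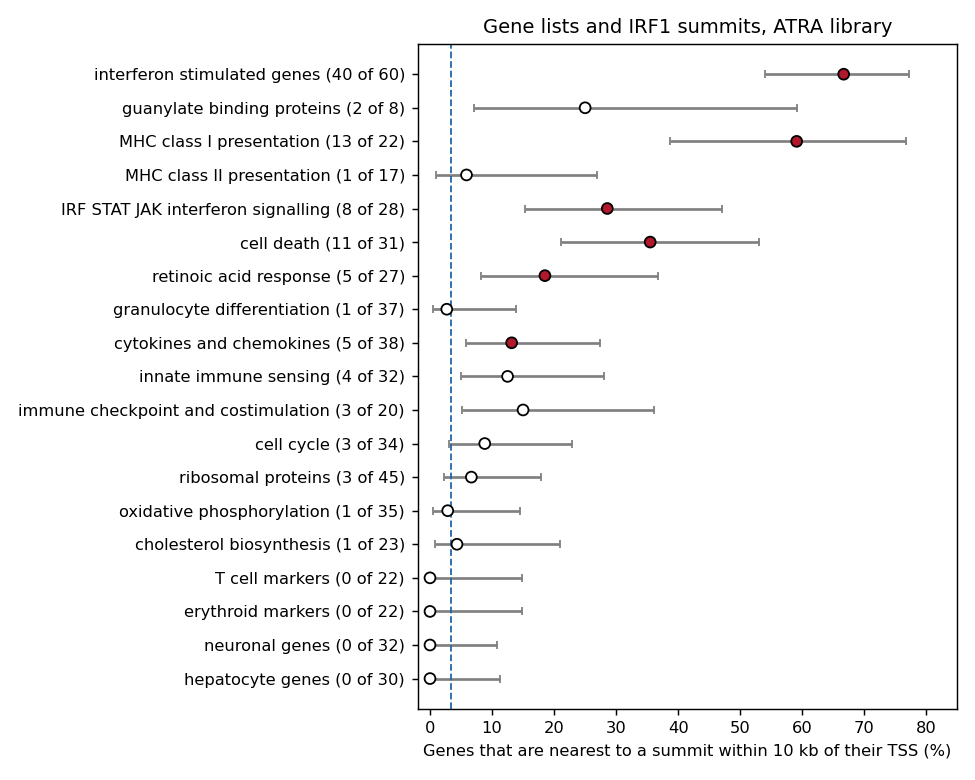
Share of each gene list (percent, x axis) that was the nearest gene of a summit within 10 kb of its TSS, with 95% Wilson intervals and the counts in the labels; filled points passed the adjusted threshold and the dashed line is the share of all protein-coding genes, 3.36%. The interferon-stimulated and MHC class I lists stand at 66.7% and 59.1%, and 4 lists of other lineages stand at 0.

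Of the regulators of interferon signalling, 8 of 28 had a summit (28.6%, 15.3 to 47.1; odds ratio 11.6, 4.41 to 27.7; adjusted Fisher's exact p = 1.27e-05). They included the feedback inhibitor SOCS1 (128), the signal transducers STAT2 (74.8) and STAT5A (21.3), the factors IRF2 (62.3), IRF7 (45.7) and IRF5 (44.0), and the kinase gene TYK2 (13.3). The cell death list held 11 of 31 (35.5%, 21.1 to 53.1; odds ratio 16.1, 6.92 to 35.3; adjusted Fisher's exact p = 1.65e-08). It included BAK1, a mitochondrial pore former (167), RIPK1, a kinase of necroptosis signalling (81.7), and GSDMD, the pyroptosis pore (73.0). CASP1, CASP4 and CASP8 also had a summit. TNFSF10, which encodes the death ligand TRAIL, had none within 10 kb.

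The retinoic acid response list held 5 of 27 genes (18.5%, 8.18 to 36.7; odds ratio 6.58, 1.94 to 17.9; adjusted Fisher's exact p = 0.00700). ASB2, a ubiquitin ligase subunit known as a retinoic acid target in this leukemia, had a score of 124 at 5567 bp from its TSS. PLAAT4 (47.1), ICAM1 (29.6), RXRA (16.8) and TNFAIP2 (14.2) made up the rest, of which PLAAT4 and ICAM1 are also known as interferon-responsive genes. CYP26A1, CYP26B1, DHRS3 and TGM2 had no summit within 10 kb. With the TSS distance limited to 1 kb the list had an odds ratio of 6.09 and an adjusted p of 0.0637 by Fisher's exact test. Cytokines and chemokines held 5 of 38 (13.2%, 5.75 to 27.3; odds ratio 4.38, 1.33 to 11.3; adjusted Fisher's exact p = 0.0268), with IL15RA, the receptor chain that presents interleukin 15 (232), the growth factor CSF1 (110), OSM (82.1), TNFSF13B (34.9) and CCL8 (20.2). This call ended under 4 other settings, among them the comparison with random lists matched on neighbourhood length (permutation, adjusted p = 0.0538).

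**Figure D4:**
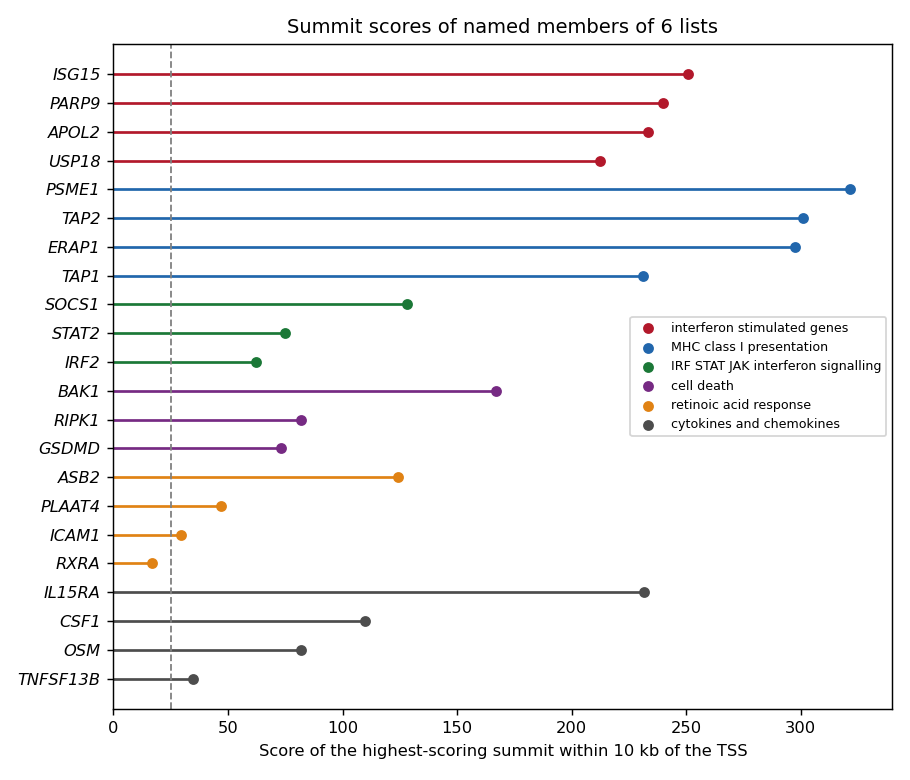
Score of the highest-scoring summit within 10 kb of the TSS (x axis, from 0) for named members of the 6 lists that passed the threshold; colours mark the lists and the dashed line is the median score of all summits, 25.2. Plotted are up to 4 members per list, those with the highest scores. They lie between 212 and 321 for the MHC class I and interferon-stimulated lists. The lowest members with a summit in these lists score 27.4 (HLA-C) and 10.4 (HERC5). RXRA, with 16.8, lies under the median.

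Granulocyte differentiation genes were not enriched, although this is the lineage into which retinoic acid drives these cells. Of 37 listed genes, NCF1 alone had a summit (41.0), and NCF1 has near-identical pseudogene copies (2.70%, 0.479 to 13.8; odds ratio 0.799, 0.0197 to 4.76; adjusted Fisher's exact p = 1). CEBPB, CEBPE, SPI1, ITGAM and CSF3R had none, and CEBPA had one only beyond 10 kb. Innate sensing genes had 4 of 32, namely NOD1 (44.0), NOD2 (43.0), MYD88 (26.2) and TLR3 (14.4), with an adjusted p of 0.0584 by Fisher's exact test. Checkpoint and costimulation genes had 3 of 20, namely VSIR (24.0), CD274, which encodes PD-L1 (22.1), and CD40 (17.1), with an adjusted p of 0.0593.

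Among lists of growth and metabolism genes, summits were found for 3 of 34 cell cycle genes, CCND1 (102), PCNA (60.3) and BUB1 (14.4), for 3 of 45 ribosomal protein genes, RPS12 (52.9), RPL37 (14.2) and RPL18 (12.2), for 1 of 35 oxidative phosphorylation genes, NDUFA9 (15.3), and for 1 of 23 cholesterol synthesis genes, SREBF2 (17.2). None of these lists passed the threshold by Fisher's exact test, the smallest adjusted p being 0.199, and the intervals were wide, as for the cell cycle list (odds ratio 2.79, 0.545 to 8.98). The T cell, erythroid, neuronal and hepatocyte lists had 0 of 106 genes with a summit within 10 kb, against 3.36% of all protein-coding genes. By the limit of 3 counts this allows a share of up to 2.83%. The difference did not pass the threshold (Fisher's exact p = 0.0529 for the 4 lists pooled, upper limit of the odds ratio 1.02). These 4 lists were pooled because each was seen to have no gene with a summit. The limit and the test therefore lean towards a low share and cannot decide whether the share is below that of other genes.

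No summit lay inside the gene of the assayed factor, IRF1 (chromosome 5, 132481609 to 132490773), and the single summit assigned to it was 24257 bp from its TSS, in an intron of the neighbouring CARINH transcript, with a score of 12.5 that exceeded 4.93% of all summits. The strong CARINH summit lay 70.7 kb from the IRF1 span. Of the fusion partners of the cell line, PML had a summit 125 bp from its TSS at chromosome 15 position 73994798 (77.2) and another in its first intron (36.2). The promoter annotation of the former names a transcript of STOML1, although PML is given as the nearest gene. RARA was the nearest gene of no summit, but 2 summits lay inside its span (chromosome 17, 40309180 to 40357643), in exons 6 and 7 of 9 of the annotated transcript, with scores of 20.7 and 42.5. RARA and RUNX1 were the only genes with more than 1 of the 30 summits classed as exon. The most distant of the 100 highest summits lay 1140042 bp from the TSS of CDH18, in an LTR12F repeat (189), 331680 bp from LINC00290 (132) and 325889 bp from DAOA (148).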

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

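The tests in this part were chosen after the values they bear on had been seen. The authors' detailed annotation, which the comparisons above do not use, named a repeat at 446 of the 1349 intronic and intergenic summits outside the chromosome 21 block. LTRs of endogenous retroviruses held 190 of these, LINEs 148 and SINEs 48. Among LTRs, LTR12F was the most frequent, with 25 summits on 15 chromosomes, a median score of 41.3 and a highest score of 189, and 23 of them lay more than 10 kb from any TSS. MER51A followed among LTRs with 18 summits, among them the one in the first intron of PML.

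If LTR summits were spread with equal chance over the 72 LTR names seen, the highest of 10000 draws gave 13 for any one, so the 25 of LTR12F argue against such a spread, although equal chance leaves out how many copies each has in the genome. Random placement of repeat reads stays open: LTR summits scored 2.41 higher in the median than summits outside repeats and CpG islands (permutation p = 0.112), and LINE and SINE summits together numbered 196. A candidate explanation is that some LTRs carry IRF binding sites, but no biological explanation was tested, because sequences were not used here.

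In the chromosome 21 block, 91 of the 133 summits had a ribosomal RNA gene as the nearest gene, a gene class that the comparisons above do not use. The block's median score was 17.6 against 26.3 for all other summits (permutation p = 0.0002). The block's summits lie close together, with a median gap of 682.5 bp, so they are not independent. The permutation of single summits leaves this out. A check of whether the summits filled the block evenly was also run and decided nothing, since 34 of 64 bins of 5 kb held a summit.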

How the results depend on the processing

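With 1 library per group, no replicate could be left out. No paired analysis was possible because each group held 1 library. The omission of the chromosome 21 block, the extended gene spans, the annotated transcript, matching on neighbourhood length and the 1 kb class of summits were chosen after seeing the data. The motif results and their alternatives were not run, nor were promoter CpG matching and distances to all RefSeq TSSs. Merging summits under 200 bp apart left 1977, omitting the block 1853, and the stricter score limit 993 by construction. The share of summits at TSSs was 27.1% within 1 kb and 39.4% within 5 kb, against 19.3% annotated as promoters. The difference in median score between promoter and other summits was 2.17 without the chromosome 21 block, where its call ended. The number of lists above background was 6, and between 4 and 7 under the alternatives. The calls of the interferon-stimulated, MHC class I, interferon signalling and cell death lists held under all 7 alternatives. Omitting the chromosome 21 block is no check of the lists, however. All its summits had a non-coding RNA as the nearest gene, so no list count could change. Adding the gene of the annotated transcript changed no list count. The retinoic acid list lost its call within 1 kb (odds ratio 6.09). The cytokine list lost it within 1 kb (4.18), with the nearest gene at any distance (2.76), with extended gene spans (2.33) and against matched lists (4.30). Guanylate binding proteins passed with the 993 highest summits (17.4), and innate sensing genes with the nearest gene at any distance (3.40). The cause was not tested. Lists without a call, each resting on 0 to 3 genes, crossed an odds ratio of 1 as follows. Within 1 kb, guanylate binding proteins, MHC class II and cholesterol synthesis fell to 0, and granulocyte and oxidative phosphorylation genes gave 1.35 and 1.43. With the 993 highest summits, checkpoint and cholesterol synthesis genes gave 0 and granulocyte genes 1.44. MHC class II gave 0.919 with the nearest gene at any distance, and with extended spans it gave 0.776 and cholesterol synthesis 0.564. Read depth per summit is unknown, so an absent summit does not show absence of binding.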

Other observations

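The tests of gene families and of exons and the comparison of scores between list genes and other genes were chosen after seeing the data, the last after the highest summits had been seen, while the tests of constitutive genes and of the dense region were written before the list results. Protein-coding genes were also grouped by the letters of their symbol, and the 676 families of at least 5 members were tested in the same way (Fisher's exact test, Benjamini-Hochberg over the families). Above the background were 6 families, of which 5 are described, and below it 1. By Fisher's exact test the PARP family of ADP-ribosyltransferases was above the background with 6 of 13 genes (PARP3, PARP8, PARP9, PARP10, PARP12 and PARP14; adjusted p = 0.00133), as were the antiviral IFIT genes with 4 of 5 (adjusted p = 0.00208), the proteasome beta subunits with 5 of 11 (PSMB1, PSMB2, PSMB8, PSMB9 and PSMB10; adjusted p = 0.00303), the apolipoprotein L genes with 4 of 6 (adjusted p = 0.00303) and the APOBEC cytidine deaminases with 4 of 11 (APOBEC3C, APOBEC3D, APOBEC3F and APOBEC3G; adjusted p = 0.0389). Olfactory receptors were below it, with 2 of 392 (Fisher's exact test, adjusted p = 0.0389). The butyrophilins had 3 of 6 (BTN3A1, BTN3A2 and BTN3A3) and did not pass (Fisher's exact test, adjusted p = 0.0532). Uncharacterised genes named LOC, which are no family, were left out after a first run; this moved the butyrophilins and the SP genes from just under the threshold to just over it, and removed the LOC genes from those below the background. Several of these families lie in gene clusters with related sequences, so their members are not independent.

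Some strong summits lay more than 10 kb from the TSS of their nearest gene. An intron of ITPK1 held the summit ranked 7 (285), and a pair of summits 66549 and 74901 bp from the TSS of IRF2BPL scored 201 and 230.3. The summit of rank 9 had PSMB1 as its nearest gene, at 93673 bp (253). These were chosen after their values were seen. The RNU2-1 small nuclear RNA array on chromosome 17 held 13 summits between positions 43233583 and 43299889, the highest at 56.7. How reads that match more than 1 place were handled is not known. Summits of this array and of the chromosome 21 block may therefore not mark binding.

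The excess of summits at interferon-stimulated and MHC class I genes was not matched by 3 lists of constitutive genes. Other lists, such as cell death and interferon signalling, also had an excess. The ribosomal protein, oxidative phosphorylation and cell cycle lists together had a share of 6.14% (7 of 114, odds ratio 1.89, 0.740 to 4.05). This lay below the lower bound of the interferon-stimulated list (54.1%). It cannot decide about general openness of active promoters, because the background of the calling is not known. If that was the control library, promoters equally open in both libraries would give no summit. Leaving out chromosome 6 between 25 and 35 Mb and the guanylate binding proteins gave an odds ratio of 61.8 (36.7 to 106) for the interferon-stimulated and MHC class I lists. The guanylate binding proteins belonged to neither list, so leaving them out changed only the genes compared against. Other neighbouring genes of the lists, such as the IFIT genes, stayed in. The dense chromosome 6 region is therefore not what carries the excess of the 2 lists. With that region included, 53 genes of the 2 lists had a summit. Their best summits scored 64.3 higher in the median than those of the 618 other genes with a summit (91.3 against 27.0, permutation p = 1e-05, the smallest the resamples can give). This argues against weak summits as the origin of the excess, although the comparison was chosen after the highest summits had been seen. Whether the treatment contributed stays open, since the control library was not analysed here and its role in the calling is not known.

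RUNX1, a regulator of blood cell formation, had summits in 5 exons, at chromosome 21 positions 34792453 (92.8), 34799397 (32.0), 34834500 (70.5), 34880691 (23.2) and 34886961 (85.1), and RARA in 2. The other 23 summits classed as exon fell in 23 different genes, and the highest count for any gene in 10000 draws weighted by gene span was 3. The 5 exon summits of RUNX1 argue against such a spread, although the draws leave out exon length and the density of summits around a gene. DNA copied from spliced transcripts, such as a cDNA construct handled near the libraries, could give summits in exons of a few genes. Of the 9 summits inside both spans 77.8% lay in exons (Wilson interval 45.3 to 93.7), against 3.20% of the 719 other exon or intron summits, but 2 lay in RUNX1 introns, with scores below those of its exon summits, and the genes were picked for this pattern. Reads across exon junctions, not used here, would decide, and binding of IRF1 within these exons stays open as well.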
